A study of Mus musculus with 2 samples.

How the data were processed

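MicroRNA sequencing was done on total RNA of mouse liver at embryonic day 16.5, with a size range below 30 per the labels. The 2 libraries were assigned to 1 group from the source label, and replicate numbers were taken from the description label. Raw counts per gene were deposited for each library, and no header names their columns. Assembly mm10 and GENCODE annotation M4 are named in the text description deposited with the counts. The aligner and the counting program are not given in the sources used here, nor is the use of molecular identifiers, so counts may include PCR copies.

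Each table held 1973 gene rows, 4 tally rows and 3 columns of counts. The first column of counts equalled the sum of the other 2 in every gene row. The stranded column with the larger total in both libraries was used as the sense-strand count, and the smaller one is called the other strand. The counts are per hairpin gene, so the 5′ and 3′ arms are not separated. Tally rows were left out of totals and tests. Of 14129766 reads tallied in replicate 1 and 12186088 in replicate 2, 42.0% and 41.9% were sense-strand counts in genes. Multimapping reads made up 28.1% and 28.2%, unmapped reads 21.8% and 21.2%, and reads outside the listed genes on either strand 4.47% and 5.00%. Because multimapping reads are outside the gene counts, miRNAs with several near-identical genomic copies may be counted low.

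Gene names, hairpin coordinates, hairpin sequences and host genes were taken from GENCODE M21 on the same mouse assembly by versionless gene identifier. Of the 1973 rows, 1894 had a match; the other 79 held 1 count over both libraries. Annotation M4 itself was not used here, so a name can differ from the one in the annotation used for counting. A host is a gene on the same strand that overlaps the hairpin. A gene was named as uncertain when at least 50% of its 18-base words occurred in another listed gene (578 rows).

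CPM were computed over the sense-strand total of each library, where 1 count is worth 0.169 CPM in replicate 1 and 0.196 CPM in replicate 2. A count of 0 was taken to allow up to 3 counts. Means and SDs are over 2 libraries. Shares of the most abundant gene have 95% Clopper-Pearson intervals. Each gene with 10 or more counts over both libraries was tested with a two-sided exact conditional binomial test against the libraries' share of the total, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 ratios and folds of single genes between the libraries were computed after adding 0.5 to each count, and their counting SEs follow from the counts alone. The common biological coefficient of variation was estimated with edgeR 4.0.16 (R 4.3.3) in an intercept-only model with TMM normalization. A quasi-likelihood test was not fitted because there is no contrast within 1 group. A sign-flip test of a ratio in 2 libraries cannot give an exact two-sided p below 0.5, so none is given for ratios between lists.

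A total of 18 lists of miRNA genes were fixed before the data were examined: hepatocyte and liver-enriched, erythroid, hematopoietic stem and progenitor, mature leukocyte, endothelial, mesenchymal, epithelial and biliary, neural, muscle, pancreas, pluripotent stem cell, let-7, miR-17-92 with paralogs, Dlk1-Dio3, H19 and Igf2 hosted, miR-30, miR-15/16 and Sfmbt2-hosted. Members without a row of their own were left out. The level of a list was its summed share of counts, and the median of its members was ranked among 10000 random lists of the same size. The shift of a list was the median log2 ratio of its tested members, ranked among 10000 random lists matched on mean level; this describes these libraries and is no test. Genes named in the text were fixed by rule: the 20 genes with the highest mean CPM, the 3 highest members of each list, and, among genes with a mean of 100 CPM or more and an adjusted p under 0.05, the 5 with the largest log2 ratio in each direction. Further members of a list are named beside its counts as examples, chosen after their values were seen.

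On simulated counts with known changes, the exact test recovered 53.1% of 49 genes changed by 1.2-fold, 60% of 50 changed by 1.5-fold, 70% of 50 changed by 2-fold and 91.8% of 49 changed by 4-fold, out of 450 genes tested, and called 9 of 252 unchanged genes (3.57%). For the list shift, log2 ratios were simulated directly, with the same normal spread for every gene. Of 100 unchanged lists of these ratios, 5 lay outside the central 95% of random lists. The simulated counts held counting error only, without spread between replicates or PCR copies. List members were drawn independently, and with an equal spread at all levels the matching on mean level was not put to the test. These rates may therefore not carry over to the data. Alternatives covered counts irrespective of strand, TMM and DESeq2 1.42.0 scaling, other count filters and pseudocounts, a total without the most abundant gene, genes with shared words left out, random lists drawn from detected genes, and each replicate left out. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.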

Results

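MicroRNA abundance was measured in whole liver of mouse embryos at embryonic day 16.5, a stage at which the liver is a major site of blood formation as well as a developing metabolic organ. MicroRNAs are short RNAs that are cut from hairpin precursors and repress the messenger RNAs they pair with. The series held 1 group with 2 biological replicates, each a pool of livers from embryos of both sexes of the B6NCrl strain. The replicate 2 pool came from 41 embryos, and the number in the replicate 1 pool is not given in the labels. The counts assigned to the annotated strand of miRNA genes came to 5930074 in replicate 1 and 5102289 in replicate 2. With 1 group, no comparison between conditions was possible, so the questions addressed here are which miRNA genes and which cell-type groups made up the fetal liver profile, and how far the 2 pools differed.

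Mir122, the hepatocyte miRNA that takes part in cholesterol and lipid metabolism, was the most abundant miRNA gene and held 21.4% ± 0.09 (SD, n = 2) of all sense-strand miRNA counts (19.6% irrespective of strand). Its share was 21.3% in replicate 1 (95% Clopper-Pearson interval 21.29% to 21.36%) and 21.5% in replicate 2 (21.42% to 21.49%). The next most abundant gene, Mirlet7g, held 5.83% ± 0.09, followed by Mir26b at 5.30% ± 0.29 and Mir126a, an endothelial miRNA hosted by Egfl7, at 4.70% ± 0.22. Each of these 3 shares lay below that of Mir122 by far more than the spread between replicates, whereas the ranges of Mirlet7g and Mir26b were separated by a smaller margin. The 10 most abundant genes together held 51.8% ± 1.31 of the counts and the 20 most abundant 68.2% ± 1.34. This ranking covers only genes with a row of their own. Counts on the strand of Mir142, which has none, came to 34005 CPM of the sense total, above Mir335 at rank 5 (31057 CPM). Those on the strand of Mir409 came to 20357 CPM, above Mir322 at rank 9 (19579 CPM). Intervals on single shares cover counting error only, since PCR copies are not independent molecules. Neither these intervals nor the SDs cover a bias between sequences that both libraries share. The ranking is therefore one of counts.

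**Figure D1:**
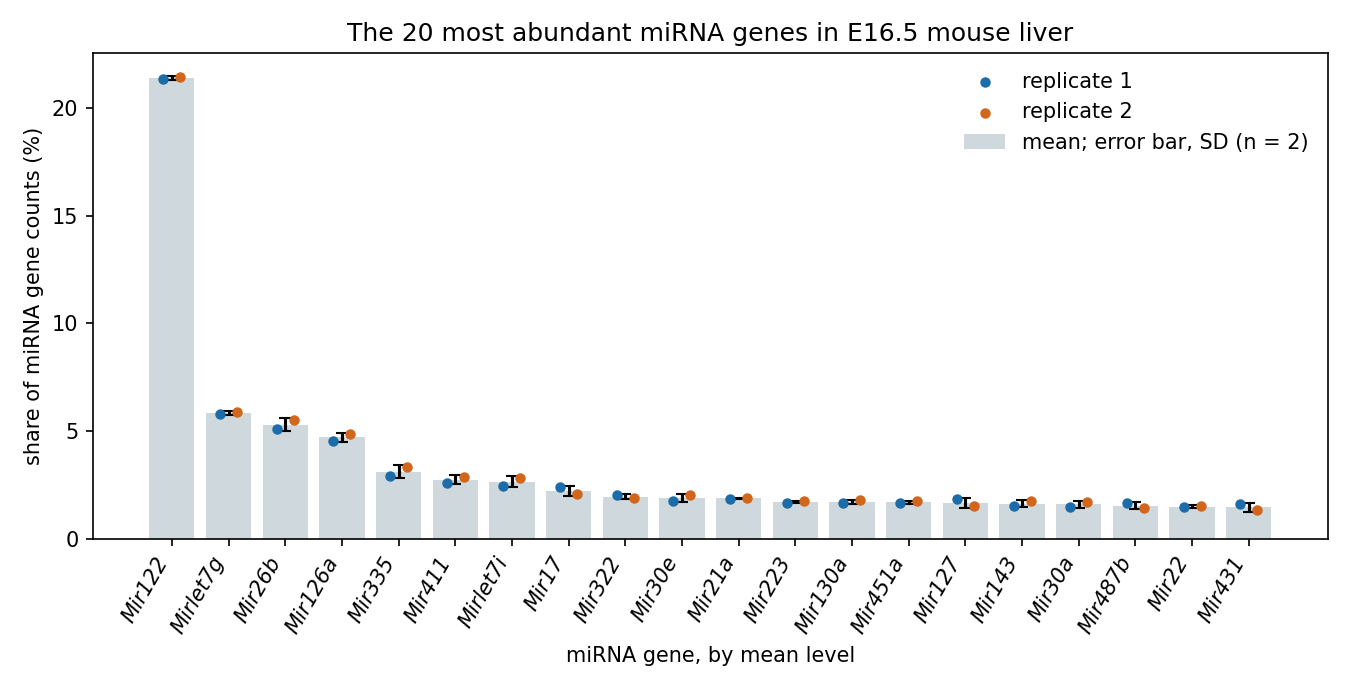
Share of miRNA gene counts (%, linear axis from 0) of the 20 most abundant miRNA genes among those with a row of their own. Bars are means of 2 replicates, error bars are SD and points are the replicates; Mir122 stands at 21.4% and no other gene has a mean above 5.83%.

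Mir122 (ENSMUSG00000065402.1) lies on chromosome 18 at 65248861 to 65248926 of mm10, plus strand, within an exon of the long noncoding RNA gene AC157910.3. Mirlet7g (ENSMUSG00000065440.1) lies on chromosome 9 at 106178840 to 106178927 in an intron of Wdr82. Mir26b (ENSMUSG00000065468.1) lies on chromosome 1 at 74394310 to 74394394 in an intron of Ctdsp1. Mir126a (ENSMUSG00000065540.1) lies on chromosome 2 at 26591357 to 26591429, overlapping an exon of Egfl7. Mir335 (ENSMUSG00000065501.1; chromosome 6, 30741299 to 30741396) lies in an intron of the imprinted gene Mest and held 3.11% ± 0.30 of the counts. Mir21a (ENSMUSG00000065455.1; chromosome 11, 86584067 to 86584158), within an exon of Vmp1, and Mir30e (ENSMUSG00000065409.1; chromosome 4, 120772606 to 120772697), in an intron of Nfyc, both held 1.88%, with SDs of 0.02 and 0.19, and could not be ranked against each other. Mir22 (ENSMUSG00000065529.1; chromosome 11, 75463716 to 75463810), in an exon of its host Mir22hg, held 1.49% ± 0.05.

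By sense-strand counts in genes, liver-enriched miRNAs formed the largest of the 18 cell-type, family and cluster lists. With other-strand counts moved to the opposite miRNA gene, their list held 20.3% and the Dlk1-Dio3 list 18.5%. Multimapping reads are in none of the lists, so shares of lists with near-identical copies may be too low in this order. The hepatocyte list (Mir122, Mir192, Mir194-1, Mir194-2 and Mir148a) held 22.1% ± 0.15 of the counts, nearly all of it Mir122. Mir192 was at 3917 ± 483 CPM (counts scaled to an equal total in each library), Mir194-2 at 1558 ± 136 CPM and Mir148a at 1546 ± 34.4 CPM. Mir192 (chromosome 19, 6264844 to 6264932) and Mir194-2 (chromosome 19, 6264643 to 6264728) are neighbours in 1 cluster, and Mir192 exceeded Mir194-2 by 2.45-fold in replicate 1 and 2.58-fold in replicate 2. Mir194-2 shares 7.25% of its 18-base words with another listed gene, and multimapping reads are not in its count. These folds may therefore be too high.

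Among blood-cell miRNAs, Mir451a and Mir144, a pair cut from 1 erythroid transcript, were at 16978 ± 722 CPM and 8041 ± 1645 CPM. With Mir486, hosted by Ank1, they gave the erythroid list 2.56% ± 0.22 of the counts, 8.64-fold below the hepatocyte list (log2 ratio -3.11 ± 0.11). This order rests on Mir122: with that gene left out of the list and the total, the erythroid list exceeded the remaining liver-enriched genes by 1.86 on the log2 scale. The list of hematopoietic stem and progenitor miRNAs held 4.30% ± 0.09, led by Mir130a (17114 ± 970 CPM), Mir99a (13641 ± 504 CPM) and Mir99b (5664 ± 1170 CPM), and 8 of its 9 members reached 100 CPM in both libraries. The remaining member, Mir125b-1 (46.5 ± 11.6 CPM), shares 11.7% of its words with another listed gene and may be counted low. The leukocyte list held 1.84% ± 0.05, of which Mir223, a miRNA of granulocytes and monocytes, made up most (17149 ± 537 CPM). Mir342 (807 ± 25.7 CPM) and Mir146 (295 ± 9.74 CPM) were lower, and the lymphocyte-enriched Mir150 was at 24.5 ± 1.06 CPM. Among random lists of genes detected at 1 CPM, the median level of the erythroid list lay at percentile 98.2, that of the stem and progenitor list at 97.52 and that of the leukocyte list, with 3 of 6 members at 100 CPM, at 67.1. Mir142, a pan-leukocyte miRNA, had no row of its own, and moving the counts found opposite the row of Mir142b to it raised the leukocyte list to 4.81% ± 0.37.

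Mir451a (ENSMUSG00000070065.1; chromosome 11, 78073170 to 78073241) and Mir144 (ENSMUSG00000065401.1; chromosome 11, 78073005 to 78073070) overlap no other annotated gene on their strand. Mir223 (ENSMUSG00000076066.1) lies on the X chromosome at 96242817 to 96242926 and Mir130a (ENSMUSG00000065484.1) on chromosome 2 at 84741115 to 84741178. Reads of miRNAs with several identical genomic copies may be in the multimapping tally, which is not split by miRNA, and not in these gene counts. Levels of let-7a, let-7c, let-7f, miR-16, miR-19b, miR-30c, miR-92a, miR-125b, miR-194 and miR-199a are therefore uncertain and may be too low. The same holds for the neural miRNAs miR-124, miR-9, miR-128 and miR-138 and the muscle miRNAs miR-1 and miR-133a. Other miRNAs with several copies may be affected too. Mir486 is overlapped by the opposite-strand gene Mir3107, and its level is uncertain too.

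Stromal and vascular miRNAs were also present. The endothelial list consisted of Mir126a only, and counts of whole liver cannot tell which cells its reads came from. The mesenchymal list held 1.72% ± 0.15, nearly all of it Mir143 (16193 ± 1603 CPM), with Mir214 at 709 ± 151 CPM and Mir145a at 204 ± 15.6 CPM. Mir143 exceeded its cluster partner Mir145a by 78.2-fold in replicate 1 and 80.7-fold in replicate 2. These are folds of counts, and their agreement does not cover a bias between sequences that both libraries share. The epithelial and biliary list (the miR-200 family and Mir141) held 0.532% ± 0.149, led by Mir429 (3624 ± 897 CPM), Mir200b (892 ± 213 CPM) and Mir200c (508 ± 260 CPM).

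Of 3 lists of clustered miRNAs with imprinted hosts or loci, 1 held a large share. The Dlk1-Dio3 cluster on chromosome 12, whose miRNAs come from the maternal allele, held 16.0% ± 0.94 of the counts, and 38 of its 44 members reached 100 CPM in both libraries. Mir411 (27453 ± 1943 CPM; chromosome 12, 109710175 to 109710256), Mir127 (16637 ± 2231 CPM; chromosome 12, 109592846 to 109592915), Mir487b (15346 ± 1556 CPM; chromosome 12, 109727333 to 109727414) and Mir431 (14632 ± 2148 CPM; chromosome 12, 109590447 to 109590537) led it. The median level of its members exceeded that of all 10000 random lists of the same size drawn from genes detected at 1 CPM. The list of miRNAs hosted by H19 and Igf2 held 0.220% ± 0.038, with Mir483 of the Igf2 intron at 2079 ± 377 CPM and Mir675 of the H19 exon at 125 ± 0.953 CPM. The families clustered in an intron of Sfmbt2 held 0.227% ± 0.025, 0.121% without genes sharing at least 50% of their words and 0% without genes sharing any; 50 of their 69 members had no count in either library. Of these 50, 40 share at least 50% of their words with another listed gene and 19 share all of them, so a count of 0 does not show that they are absent. The most abundant member, Mir467d (662 ± 62.6 CPM), is uncertain because 66.2% of its 18-base words occur in another listed gene. Mir467e (583 ± 18.9 CPM) and Mir467c (558 ± 95.7 CPM) followed. They share 45.7% and 46.25% of their words, just below the 50% limit, so their levels are little more certain.

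The let-7 family, which accumulates as tissues differentiate, held 10.04% ± 0.39, led by Mirlet7g, Mirlet7i (26376 ± 2591 CPM) and Mirlet7d (7571 ± 275 CPM). It held 1.53% when genes sharing any 18-base word were left out, a setting that removes Mirlet7g and Mirlet7i. Mirlet7a-1, Mirlet7c-1 and Mirlet7f-2 share 27.3%, 11.7% and 12.1% of their words with other listed genes, and multimapping reads are not in their counts. The order of the let-7 members is therefore uncertain, and the share of the family may be too low. The proliferation-associated miR-17-92 cluster and its paralogs held 5.93% ± 0.43, led by Mir17 (22237 ± 2187 CPM), Mir20a (10907 ± 352 CPM) and Mir93 (10347 ± 1612 CPM). Mir17 exceeded Mir19b-1, the lowest member of the same transcript, by 2044-fold and 1885-fold in the 2 libraries, but Mir19b-1 shares 11.4% of its words with another listed gene, and multimapping reads are not in its count. The miR-30 family held 3.91% ± 0.32 (Mir30e 18829 ± 1936, Mir30a 15944 ± 1713 and Mir30d 4077 ± 394 CPM) and the miR-15/16 family 3.55% ± 0.14 (Mir322 19579 ± 1064, Mir15a 8882 ± 81.1 and Mir16-1 3567 ± 114 CPM). Without genes sharing any word, which leaves out Mir30e and Mir30a, the miR-30 family held 0.508%. Within other transcripts, Mir451a exceeded Mir144 by 2.39-fold and 1.90-fold, Mir93 exceeded Mir25 by 14.3-fold and 14.6-fold, and Mir99b exceeded Mir125a by 6.30-fold and 5.16-fold, in replicates 1 and 2. Folds within a transcript are of counts and may hold a bias between sequences that both libraries share.

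miRNAs of tissues other than liver and blood held small shares of the counts. The neural list held 0.0319% ± 0.0008 and the pluripotent stem cell list 0.0121% ± 0.0007. Among random lists drawn from all 1973 rows, most of which had no count, the median levels of their members lay at percentiles 99.7 and 99.8, those of the muscle list at 98.6 and those of the pancreas list at 91.5. Among random lists of genes detected at 1 CPM in both libraries, the same lists lay at percentiles 3.63, 2.08, 5.92 and 9.54. The neural, pluripotent and muscle lists include members without a count, which can lower their percentiles against detected genes. All 4 members of the pancreas list were detected at 1 CPM in both libraries. Mir128-1 (124 ± 10.3 CPM), Mir132 (84.6 ± 5.38 CPM) and Mir137 (39.4 ± 19.4 CPM) led the neural list. Mir128-1 shares 11.3% of its words with another listed gene, and multimapping reads are not in its count. The copies of miR-124 and miR-9 with a row had 0 to 7 counts in a library and share 23.3% to 58.2% of their words with other listed genes, so the neural level is uncertain and may be too low; it was 0.0166% without genes sharing any word. Mir294 (27.9 ± 1.29 CPM), Mir293 (27.3 ± 3.64 CPM) and Mir302d (17.4 ± 2.13 CPM) led the pluripotent list. The muscle list held 0.178% ± 0.068, mainly Mir206 (1577 ± 669 CPM), with Mir499 at 144 ± 1.14 CPM and Mir208b at 44.3 ± 10.5 CPM. The pancreas list held 0.175% ± 0.050, mainly the endocrine miRNA Mir375 (1732 ± 501 CPM), with Mir217 at 10.9 ± 3.20 CPM and Mir216b at 5.31 ± 2.51 CPM.

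**Figure D2:**
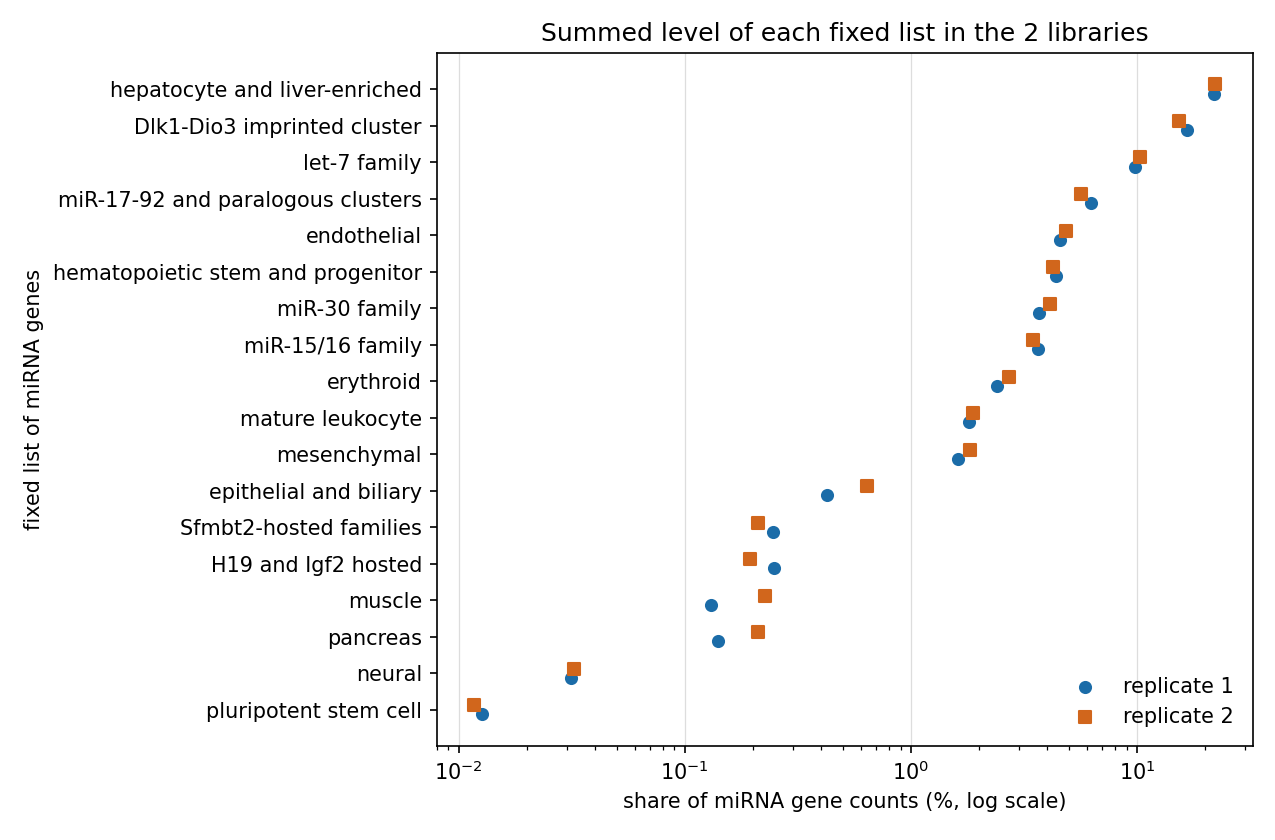
Summed share of miRNA gene counts (%, log axis) for the 18 fixed lists, with 1 point per replicate. The lists run from 22.1% for hepatocyte and liver-enriched genes to 0.0121% for pluripotent stem cell genes; the muscle, pancreas and epithelial lists show a visibly wider gap between replicates.

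Across the 1973 gene rows, 397 genes were at 1 CPM or more in both libraries, 177 at 100 CPM or more and 25 at 10000 CPM or more. A gene without a count lay below 0.506 CPM in replicate 1 and 0.588 CPM in replicate 2.

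The 2 libraries differed in miRNAs of the epithelial and biliary list, all 5 of which were higher in replicate 2, and in the Dlk1-Dio3 cluster, where 31 of 43 tested members were lower in replicate 2 past the exact test. Among genes with a mean of 100 CPM or more, the largest difference was in Mir215, an intestine-enriched miRNA of the miR-192 family, with 75 counts in replicate 1 and 1920 in replicate 2 (log2 ratio 4.89, counting SE 0.17, 29.6-fold). Mir200c was 2.14-fold higher in replicate 2 (log2 1.09, counting SE 0.04), Mir206 1.86-fold (log2 0.89), Mir375 1.51-fold (log2 0.60) and Mir200a 1.48-fold (log2 0.56). Mir194-1, the neighbour of Mir215 on chromosome 1, had 83 counts in replicate 1 and 259 in replicate 2; it was singled out after its values were seen. Among genes at that level, those lower in replicate 2 by the largest ratios were Mir486 (log2 -0.66), Mir3074-1 (-0.66), Mir328 (-0.63), Mir674 (-0.63) and Mir433 (-0.63), each between 1.54-fold and 1.58-fold.

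These 10 genes, the 5 with the largest ratio in each direction among genes of 100 CPM or more, had exact binomial adjusted p-values of 8.84e-16 for Mir3074-1, 3.45e-19 for Mir200a and 5.47e-21 for Mir328, and smaller values for the others. Mir215 (ENSMUSG00000065562.1) lies on chromosome 1 at 185313581 to 185313692 in an exon of the antisense RNA gene 2010103J01Rik. Mir200c (ENSMUSG00000065462.2) lies on chromosome 6 at 124718322 to 124718390, Mir206 (ENSMUSG00000065559.1) on chromosome 1 at 20679010 to 20679082, Mir375 (ENSMUSG00000065616.2) on chromosome 1 at 74900658 to 74900721 and Mir486 (ENSMUSG00000070084.3) on chromosome 8 at 23142555 to 23142682 in an intron of Ank1.

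All 5 members of the epithelial and biliary list were higher in replicate 2, with a median log2 ratio of 0.56, above the medians of all 10000 random lists matched on mean level. All 5 passed the exact test over all genes and, adjusted over the list alone, 5 passed as well. The largest ratio in the list was that of Mir141 (log2 1.56, counting SE 0.10). In the pancreas list the median was 0.60 (percentile 99.4), with Mir375 higher and Mir216b lower in replicate 2 past the test, and 3 of 4 members past the test adjusted over the list alone. That percentile fell to 93.6 over genes of 10 CPM or more. In the muscle list the median was 0.42 (percentile 96.5), and Mir206 and Mir208b were higher past the test (2 genes adjusted over the list alone). Over genes of 10 CPM or more the muscle median was 0.23 (percentile 89.5).

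Members of the Dlk1-Dio3 cluster moved the other way. Of 43 tested members, 31 were lower and 3 higher in replicate 2 past the exact test (34 in either direction adjusted over the list alone), with a median log2 ratio of -0.22 at percentile 0.03 of the matched random lists. Mir433, Mir770 (log2 -0.55) and Mir370 (log2 -0.50) were among the lower members, whereas Mir411 was higher (log2 0.14). Scaling by TMM moved the cluster's median to -0.14, still at percentile 0.05.

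The remaining lists had medians inside the central 95% of random lists. The hepatocyte list had a median log2 ratio of 0.18 (percentile 95.5; 99.1 after a GC correction and 84.9 without genes sharing any word), with 4 of 5 members higher past the test; adjusted over the list alone, Mir148a also passed, as lower (log2 -0.05), which made 5. The erythroid list had a median of 0.09 (percentile 85.2), with Mir451a and Mir144 higher and Mir486 lower past the test (3 adjusted over the list alone, in either direction). Percentiles were 90.1 for the mesenchymal, 89.2 for the let-7, 87.2 for the miR-15/16, 82.4 for the leukocyte, 68.9 for the pluripotent, 56.8 for the neural, 51.0 for the stem and progenitor, 46.2 for the H19 and Igf2, 34.4 for the miR-30, 11.6 for the miR-17-92 and 4.19 for the Sfmbt2 lists, the last of which lay between percentiles 0.02 (GC correction) and 22.3 (no filter beyond 1 count) over the alternatives. The medians of the stem and progenitor, leukocyte, neural, pluripotent, miR-17-92, miR-30 and miR-15/16 lists changed sign under at least 1 alternative, so no direction is given for them. Percentiles ranged from 22.3 to 69.8 for the pluripotent and from 28.3 to 77.6 for the neural list. Without genes sharing any word, the miR-17-92 median turned from -0.18 to 0.02 (percentile 85.2), and the miR-15/16 median from 0.02 to -0.11 (percentile 42.7). Genes past the test when adjusted over the list alone numbered 5, 7, 7, 1, 0, 1, 8, 1, 4, 12 and 7 in the same order. Of the 17 lists with 2 or more tested members, 3 lay outside the central 95% of random lists (epithelial, pancreas and Dlk1-Dio3). Members of a cluster are not independent, so this ranking describes the libraries and is no test.

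**Figure D3:**
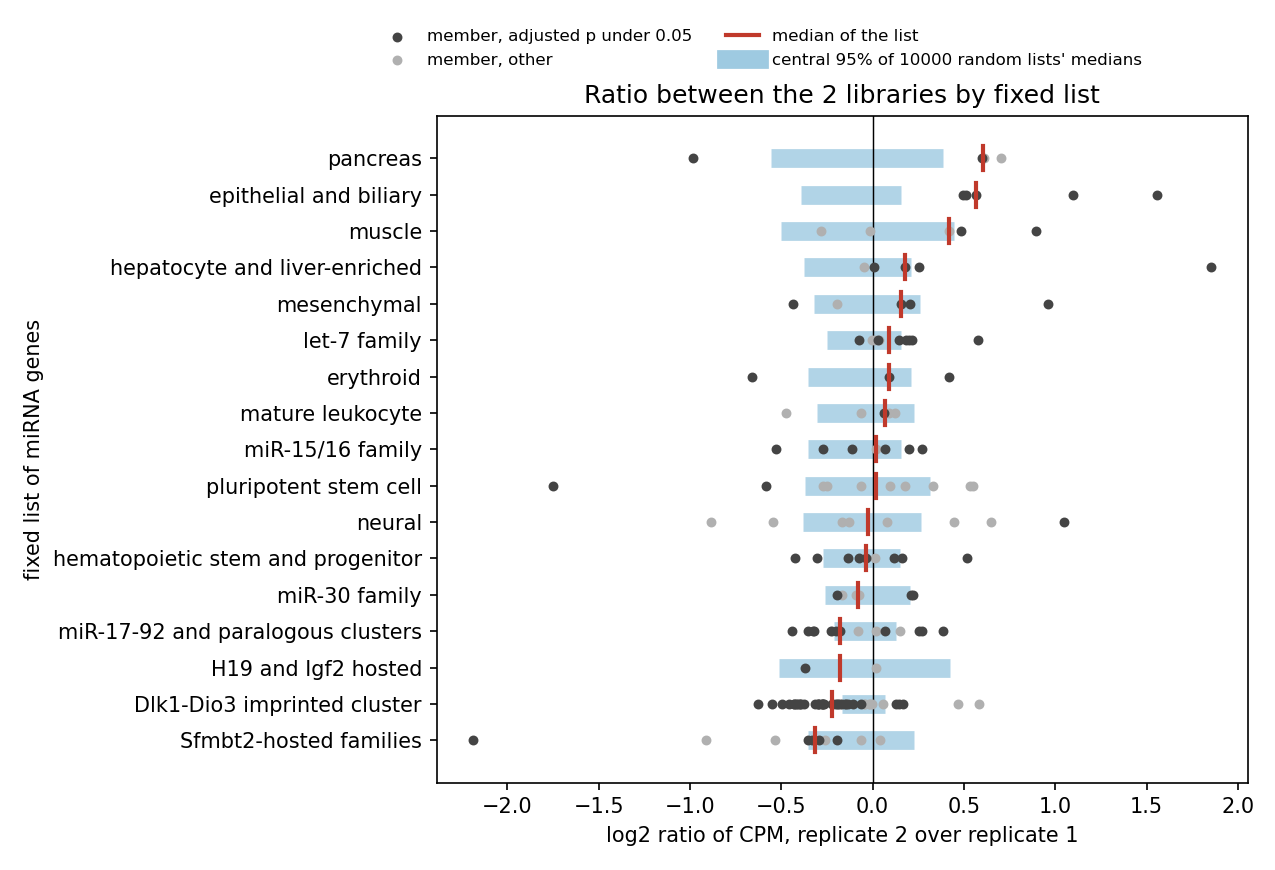
Log2 ratio of replicate 2 over replicate 1 for each tested member of 17 fixed lists (points), with the list median (red bar) and the central 95% of medians of 10000 matched random lists (blue band). The epithelial and pancreas medians (0.56 and 0.60) lie above their bands and the Dlk1-Dio3 median (-0.22) lies below its band.

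Over all 440 genes tested, 196 differed between the 2 libraries by more than counting error (two-sided exact binomial test, Benjamini-Hochberg adjusted p under 0.05), 77 higher and 119 lower in replicate 2. The split was 98 higher and 97 lower under TMM or DESeq2 scaling, which moved log2 ratios by 0.08. Of the 196 genes, 27 differed by 2-fold or more, and among the 183 tested genes with a mean of 100 CPM or more only Mir215 and Mir200c did. Of these 183 genes, 173 lay within 1.5-fold, and the median absolute log2 ratio was 0.20. Across genes, which are not independent replicates, Pearson's r of log2(CPM + 1) was 0.991 and Spearman's rho 0.979. The common biological coefficient of variation was 0.229. This test compares the 2 libraries and not conditions.

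A further 524695 counts in replicate 1 and 456675 in replicate 2 were assigned to the strand opposite to the annotated gene, 8.13% and 8.22% of all gene counts. They lay almost entirely in a few rows, led by Mir142b (34005 ± 3529 CPM of the sense total), Gm24321 (20357 ± 3140) and Gm25252 (14329 ± 2120).

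**Figure D4:**
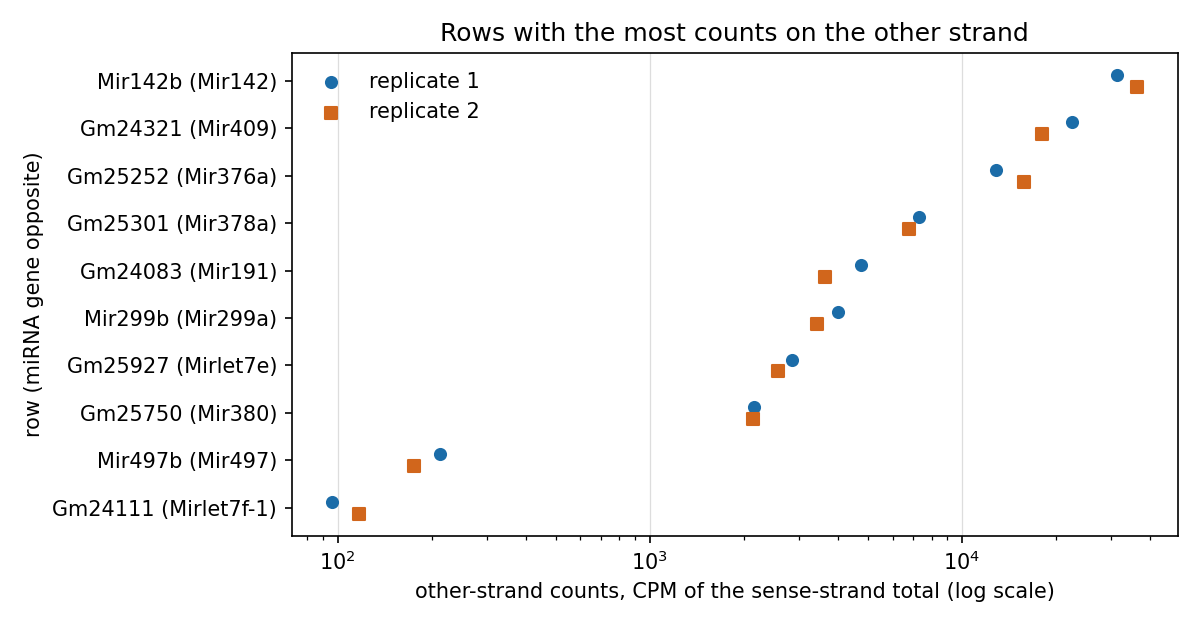
Counts on the other strand as CPM of the sense-strand total (log axis) in the 10 rows that hold the most, with 1 point per replicate; the miRNA gene annotated on the opposite strand is in parentheses. The row of Mir142b leads with a mean of 34005.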

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

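The tests on the strand of the counts, on hairpin GC content across genes, and on pancreas and muscle genes were chosen after the results they address were seen. The tests on TMM scaling, on GC content in the epithelial list and on a further gut list were written before their results were seen. The design holds 1 group and so gives no biological explanation to test; other tissue in a pool was tested as a mixed sample.

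Counts on the strand opposite to the annotated gene reached 524695 in replicate 1 and 456675 in replicate 2, far above the 3 counts that a count of 0 allows. The main settings did not use these counts. They entered only where other-strand counts are named or moved, and in the alternative irrespective of strand. Over both libraries, the row of Mir142b held 373085 of them, Gm24321 226423, Gm25252 156842, Gm25301 77814, Gm24083 46859, Mir299b 41348, Gm25927 30110, Gm25750 23706, Mir497b 2160 and Gm24111 1168. Loss of strand information in the libraries was argued against, because the median other-strand share of the 20 most abundant genes was 0.000127%. A candidate explanation is that these reads come from a miRNA gene that M21 annotates on the opposite strand and that has no row here: 99.9% of the other-strand counts lay in 27 such rows, among them those opposite Mir142, Mir409, Mir376a, Mir378a, Mir191, Mir299a and Mirlet7e. Why those genes have no row stays open, because annotation M4 was not used here.

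Ratios between the 2 libraries exceeded counting error in 196 of 440 genes. Scaling set by a few abundant genes was argued against as the cause of that number, since 195 genes were still called under TMM. The split by direction did depend on scaling, with 77 higher and 119 lower in replicate 2 under the total, and 98 and 97 under TMM. Hairpin GC content may account for a part of the differences: over the 183 genes of 100 CPM or more, Spearman's rho of GC against the log2 ratio was -0.32 (permutation p = 3e-05 of 100000 permutations; Pearson's r -0.21), across genes that are not independent. GC content as the whole cause was argued against, as a linear trend, because the correction removed 7.72% of the variance of the log2 ratio without Mir215 (95% bootstrap interval 1.84% to 17.8%). Differences between the pools and between library preparations stay open, as the labels give no batch.

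The 5 epithelial and biliary genes were higher in replicate 2, together with Mir215. GC content was argued against for this list, whose median log2 ratio was 0.59 after the correction. Pancreas and muscle tissue in the replicate 2 pool could not be decided. Of the 6 members with a counting SE under 0.28, 50% were higher past the exact test (Mir375, Mir206 and Mir208b) and none lower past it. An earlier form of the test over all 9 tested members counted against it: 33.3% were higher and 1, Mir216b, lower past the test. That form was replaced because it included members with few counts. The SE limit was set after the values were seen and left out Mir216b (42 and 18 counts, counting SE 0.40). The absence of lower members past the test follows from that choice. Intestinal tissue could not be decided either: of 6 tested genes in a further gut list, 3 (50%) were higher past the test (Mir147, Mir182 and Mir96) and 1, Mir31, was lower past it, and all 6 were already present in replicate 1, at 5.90 to 493 CPM. A different share of bile duct cells between the pools cannot be separated from these with the genes at hand.

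Multimapping reads, which belong to no gene in the tables, numbered 3968471 in replicate 1 and 3433679 in replicate 2. Reads outside the listed genes on either strand numbered 632302 in replicate 1 and 609043 in replicate 2. Both tallies lie above the 3 counts that a count of 0 allows and were not used in the comparisons.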

How the results depend on the processing

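Of 370 recomputed values for 85 results, 256 stayed within the spread or on their side of the threshold, 90 moved by more than the spread, 12 reversed, 2 became stronger and 10 weaker. The alternatives that moved other-strand counts, left out any shared word or corrected for GC were chosen after seeing the data. Genes called with 2-fold or more fell from 27 to 9 over genes of 10 CPM or more, because fewer low genes are tested. Pearson's r was 0.989 with that filter and 0.994 with a pseudocount of 5. The share of the 10 most abundant genes was 49.016% irrespective of strand, 49.017% with other-strand counts moved and 41.1% without Mir122. The hepatocyte list held 20.291%, 20.292% and 0.897% under the same 3 settings, and 27.3% without genes sharing any word. The erythroid list held 3.26% without Mir122 and 3.19% without shared words; the latter setting took the let-7 family to 1.53%, miR-30 to 0.508% and the neural list to 0.0166%, by leaving out their members. Leaving out Mir122 removed it from the total and from its list, and by that construction reversed the log2 ratio to the hepatocyte list for the erythroid (1.86), stem and progenitor (2.61), leukocyte (1.38), endothelial (2.74), mesenchymal (1.29), let-7 (3.83), miR-17-92 (3.07), Dlk1-Dio3 (4.51), miR-30 (2.47) and miR-15/16 (2.33) lists. Ratios of mean log2 levels, where each member counts equally, were 0.93 for the erythroid and 4.39 for the endothelial list. The hepatocyte shift became 0.26 (percentile 99.1) after GC correction and 0.01 (84.9) without shared words, and the Sfmbt2 shift -0.46 (0.02) after GC correction and -0.26 (22.3) with no filter beyond 1 count; the cause of this and of the moves in r was not tested. Without each replicate in turn, genes at 1 CPM numbered 414 to 450 and genes at 100 CPM 182 to 184; the 10 most abundant genes held 50.9% to 52.7%, the hepatocyte list 22.0% to 22.2% and the erythroid list 2.41% to 2.72%, with log2 ratios of -3.19 to -3.03, and the Mir451a to Mir144 log2 ratio was 0.93 to 1.26. With 2 libraries, a mean never moves by 1 SD when 1 is left out, so this says nothing about stability. The epithelial shift stayed between 0.56 and 0.65 and the Dlk1-Dio3 shift between -0.27 and -0.14 over 8 alternatives each. No paired analysis was possible because there is 1 group. Depth limits genes near the floor of 0.506 and 0.588 CPM.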

Other observations

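Several miRNA genes outside the fixed lists were as abundant as members of the lists; they were chosen after their values were seen. Mir23a was at 12861 ± 1052 CPM (SD, n = 2) and its paralog Mir23b at 9049 ± 9.24 CPM. Mir101b, in an intron of Rcl1, was at 7757 ± 588 CPM, and Mir139, in an intron of Pde2a, at 5739 ± 473 CPM. Mir351, beside Mir322 on the X chromosome, was at 2035 ± 34.9 CPM.

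Among miRNA genes that have no row of their own but an opposite-strand row, the counts, as CPM of the sense total, were 34005 ± 3529 on the strand of Mir142, 20357 ± 3140 on that of Mir409, 14329 ± 2120 on that of Mir376a and 7035 ± 340 on that of Mir378a, a miRNA of the Ppargc1b locus. With the other-strand counts moved to these genes, the Dlk1-Dio3 cluster held 18.5% ± 1.01 of the counts in place of 16.0%, and the let-7 family 9.48% ± 0.33 in place of 10.04%. The row named Mir3071 in M21 held 8016 and 8235 sense counts and only 13 and 21 counts on the strand of Mir136, with the name and strand of that row in M4 not analysed here.

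In the further gut list, Mir31 was at 493 CPM in replicate 1 and 457 in replicate 2, Mir10b at 386 and 396, Mir182 at 216 and 317, Mir96 at 96.3 and 121, and Mir147 at 18.2 and 34.3. Mir196a-2 was at 5.90 and 5.49 CPM, and Mir196a-1 had 1 count in each library.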
